A study of Homo sapiens with 6 samples.

How the data were processed

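RNA-seq of HaCaT keratinocytes with NAT10 overexpression plasmids (3 libraries) and with an empty vector (3 libraries) was used. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a GenSeq kit that keeps the strand. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, HTSeq 0.9.1, edgeR without a version, and the genome build GRCh38. Their roles and settings, the annotation version, the strand setting of the counting and any filter are not given in the sources used here.

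The deposited table holds raw read counts per gene for each library, per the file headers, and these counts were the only values analysed. It holds 15951 genes, all protein-coding and each with at least 1 count, and 1 line of it had been emptied and was not used here. The 6 columns of normalized values in the table were not used here, because the counts of the same libraries were. Gene symbols are those of the table, and 12 symbols belong to more than 1 identifier. GENCODE release 29 on GRCh38 gave coordinates, and 15948 genes were matched by identifier. Transcript length and GC content were taken from the longest protein-coding transcript, which need not be the one expressed. The acetylated RNA immunoprecipitation that the study also made was not analysed here.

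Groups came from the sample labels. The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10, which left 12079, libraries were scaled by TMM, and the quasi-likelihood test compared the 2 groups with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, were called changed, and those with a fold of at least 2 were counted separately. Standard errors of log2 fold changes were computed from the fold change and the F statistic. CPM were computed on TMM-scaled library sizes, with the SD over 3 libraries. The total counts were 28774931, 26263081 and 29357925 for vector and 29565749, 29035526 and 18143628 for NAT10, and the biological coefficient of variation was 27.6%, so spread between libraries set the precision of well-counted genes. Pairs of libraries in a group differed by at least 24.0 in chi-square per degree of freedom, so none was taken as a duplicate.

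Of 27 gene lists, the 22 with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and adjustment over the lists. The tests were repeated with an estimated correlation and with fry, which asks whether a list's genes move one way and does not compare them with other genes. With the estimated correlation 0 of the lists passed in camera (lowest unadjusted p = 0.0449, RNA modification), and fry called 14. Members were counted as called over all tested genes and again with p adjusted over the list alone.

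Named genes were NAT10, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 2 CPM and no overlap between groups, the 5 called genes of highest mean level, and up to 4 members of each list with the smallest adjusted p. Where fewer than 2 members of a list were called, the 2 of highest level were given as values. The values of 1 gene that the rule names are not reported here. From the largest rises and falls, but not from the other named genes, the rule left out clone-like and predicted gene names. These included any name that ends in P followed by digits, which also removed BMP3 from the 12 largest falls.

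Alternatives were DESeq2 1.42.0, DESeq2 size factors, upper-quartile scaling, no filter, a filter of at least 10 counts in all 6 libraries, limma-voom, the replicate number as a block, other thresholds, each library left out in turn, and a correction for GC content and length. The correction fitted each library's log2 deviation by loess (span 0.3) on GC content and length and entered the fit as an offset. Leaving out libraries under DESeq2 and under the correction, and the correction with the block, were added after the data were seen. Pathway and process terms were also tested after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

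The edgeR test was tested on simulated counts for this comparison, with 50 genes changed at each of 4 folds. Without a library trend, 2, 4, 31 and 45 of 50 were recovered at folds of 1.5, 2, 3 and 4, with 4 false calls among 11977 genes. With the GC and length trends of the libraries added, 0, 0, 9 and 19 were recovered without correction and 5 of 11972 genes were false calls. After correction 2, 9, 33 and 43 were recovered, with 8 false calls. The simulated spread was that of the uncorrected fit, which already holds the trend differences within groups, so adding the trends counted these again. Recovery may thus be too low, and the false calls do not measure how many calls in the data stem from the trends.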

Results

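Messenger RNA was profiled by RNA-seq in HaCaT cells, a spontaneously immortalized line of human keratinocytes, the main cell type of the epidermis. The cells carried either NAT10 overexpression plasmids or an empty vector. NAT10 is the acetyltransferase that forms N4-acetylcytidine on RNA, and the comparison asked which mRNAs differ when its level is raised. Each group held 3 libraries made from total RNA, and counts for 15951 protein-coding genes were used. The vector libraries held 28774931, 26263081 and 29357925 counts and the NAT10 libraries 29565749, 29035526 and 18143628, so NAT10 replicate 3 was the shallowest. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical.

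NAT10 itself (ENSG00000135372, chromosome 11, 34105602 to 34147670, GRCh38) was at 199.7 ± 13.05 CPM in the vector libraries and 268.8 ± 16.25 CPM in the NAT10 libraries (SD, n = 3 each), a ratio of 1.35. Gene counts do not separate transcripts of the plasmid from those of the endogenous gene, and a plasmid transcript may lack the annotated untranslated regions, so the ratio is an uncertain measure of the overexpression. All 3 NAT10 libraries, at 283, 251 and 273 CPM, lay above the 3 vector libraries, at 208, 185 and 206 CPM. The log2 fold change of 0.43 ± 0.13 (SE) did not pass the test across all genes (edgeR quasi-likelihood, adjusted p = 0.0686). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 can give. The value passed with DESeq2 (adjusted p = 0.0428), after correction for GC content and length (edgeR adjusted p = 0.0123) and without NAT10 replicate 2 (edgeR adjusted p = 0.0120). It did not pass in the other alternatives that kept all 6 libraries without that correction, where the adjusted p from edgeR or limma-voom lay between 0.0560 and 0.102, and over all alternatives run the adjusted p from edgeR, DESeq2 or limma-voom lay between 0.00130 and 0.268.

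The NAT10 libraries held more mRNA for 64 of 73 ribosomal proteins, 18 of 46 ribosome biogenesis factors, 9 of 19 immediate early genes, 9 of 28 genes of the integrated stress and unfolded protein response and 10 of 39 interferon-stimulated genes, and less for the keratins KRT4, KRT13 and KRT15. These 5 lists passed in camera with a preset correlation between genes, but no list passed with an estimated correlation (camera adjusted p = 0.297 to 0.313 for the 5). OASL, an interferon-induced protein of the oligoadenylate synthetase family, rose 13.5-fold, from 7.26 ± 2.21 to 98.1 ± 14.8 CPM (SD, n = 3). FOSL1, a subunit of the AP-1 transcription factor, rose 5.14-fold, and RPL27 of the large ribosomal subunit rose 3.78-fold. KRT13, a keratin of stratified mucosal epithelia, fell 9.36-fold, from 346 ± 58.5 to 37.0 ± 9.34 CPM. Of 12079 genes tested, 1794 changed (edgeR, Benjamini-Hochberg adjusted p under 0.05), of which 1033 rose and 761 fell, and 991 changed by at least 2-fold, 481 up and 510 down. The groups did not overlap for 4879 genes (40.4%). The average over all splits into 3 and 3 is 10%, but genes that move together can exceed it in a single split. The split that put vector replicate 1 with NAT10 replicates 1 and 3 had 2432 genes at an unadjusted edgeR p under 0.05. In the other splits that mix the groups this number lay between 28 and 294. Leaving out vector replicate 1, vector replicate 2 or NAT10 replicate 3 ended every edgeR call made without a correction for GC content and length, members of the gene lists included, with 3378, 2624 and 2631 genes still at an unadjusted p under 0.05 and 1975, 1317 and 1309 genes called by DESeq2. With that correction edgeR called 3898 genes on all libraries, 2137, 1498 and 1798 with the same 3 libraries left out in turn, and 2736 without vector replicate 3. Without vector replicate 3 and without the correction the 6 edgeR calls were OASL, KRT13, KRT15, CCDC80, PADI1 and AOC1, whereas 1556 genes were called without NAT10 replicate 1 and 5705 without NAT10 replicate 2.

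**Figure D1:**
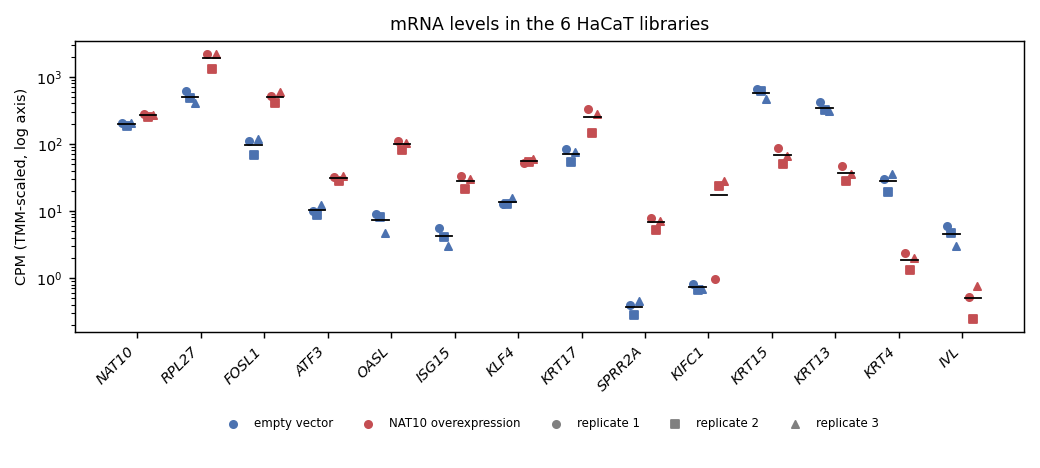
CPM (TMM-scaled, log axis) of 14 genes in each library, with blue for the empty vector, red for NAT10 overexpression, the marker shape for the replicate number and a black bar for the mean of 3 libraries. NAT10 lay at 185 to 208 CPM with vector and 251 to 283 CPM with NAT10, OASL and KRT13 were far apart between groups, and KIFC1 was at 0.969 CPM in NAT10 replicate 1 against 23.3 and 28.0 CPM in the other NAT10 libraries.

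Cytosolic ribosomal protein mRNAs rose almost as a class. Of 73 tested, 64 rose and none fell (71 and 0 adjusted over the list alone), and the median log2 fold change was 1.08 (camera adjusted p = 8.08e-27; adjusted p = 0.306 with an estimated correlation). RPL27 rose by 1.92 ± 0.26 on the log2 scale (SE), RPS15A by 1.85 ± 0.23, RPL14 by 1.21 ± 0.13 and RPL11 by 1.18 ± 0.16. These genes took 6.52%, 5.94% and 5.16% of the counts in the vector libraries and 11.5%, 8.38% and 10.9% in the NAT10 libraries. Transcript length moved with the groups too: short transcripts were relatively abundant in the NAT10 libraries, with a median log2 fold change of 0.58 in the 10% of genes with the shortest transcripts and -0.61 in the 10% with the longest. NAT10 replicate 2 stood apart from the other NAT10 libraries. Across genes, which are not independent replicates, the Spearman correlation of a library's deviations with length was 0.06 in it against -0.48 and -0.47 in NAT10 replicates 1 and 3, and with GC content -0.65 against 0.69 and 0.44. After a correction of each library for GC content and length, 49 of the 73 rose, none fell and the median was 0.54, with RPL27 at 1.10 ± 0.12.

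**Figure D2:**
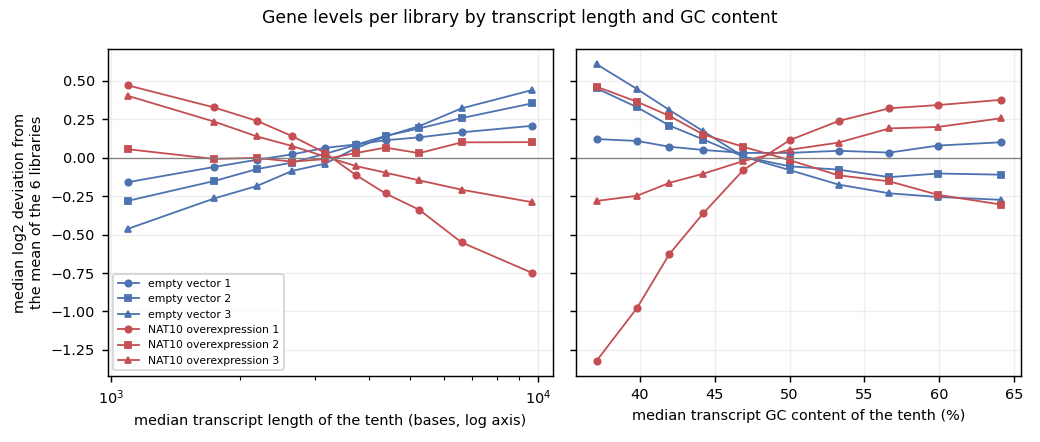
Median log2 deviation of a library from the mean of the 6 libraries (vertical axis) for bins of 10% of the tested genes ordered by transcript length in bases (left, log axis) or GC content in percent (right), with blue lines for vector, red for NAT10 and marker shapes for the replicate number. In the bin of shortest transcripts the NAT10 libraries lay at 0.47, 0.06 and 0.40 and the vector libraries at -0.16, -0.28 and -0.46, and in the bin of lowest GC content NAT10 replicate 1 stood apart at -1.32.

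The ribosome biogenesis list, factors that process and assemble ribosomal RNA in the nucleolus, moved the same way, with 18 of 46 tested members up and none down (24 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 2.91e-08; adjusted p = 0.297 with an estimated correlation). NOP16 rose 2.57-fold, RRP9 2.56-fold, UTP14A 2.21-fold and NOP56 1.84-fold. After the GC and length correction 31 members rose, with a median of 0.57. Among 29 enzymes and cofactors of RNA modification, 7 rose and none fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00574; adjusted p = 0.297 with an estimated correlation). METTL1, a tRNA methyltransferase, rose by 1.02 ± 0.19 on the log2 scale (SE), BUD23 by 0.96 ± 0.20, TRMT1 by 0.91 ± 0.21 and EMG1 (ENSG00000126749) by 0.79 ± 0.18. After the correction METTL1, BUD23 and TRMT1 were lower, at 0.67, 0.40 and 0.66, and EMG1 was at 0.85. For RNA modification 4 rose without NAT10 replicate 1, 12 rose and 2 fell without NAT10 replicate 2, and 11 rose after the correction, where the median was 0.32 against 0.26.

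Immediate early genes were listed as mostly transcription factors and phosphatases, many but not all of which respond within minutes to growth factors or stress. These genes gave 9 rises and no fall among 19 tested (14 and 0 adjusted over the list alone). Their median was 1.12 (camera adjusted p = 2.58e-08; adjusted p = 0.297 with an estimated correlation), and 12 members rose after the correction, with a median of 0.74, and 15 without NAT10 replicate 2. NR4A3 rose 6.38-fold from a low level of 0.316 ± 0.0450 CPM, ATF3 2.98-fold and DUSP6 2.17-fold, beside FOSL1. ATF3 is also in the list of the integrated stress and unfolded protein response, where 9 of 28 members rose and none fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.000164; adjusted p = 0.306 with an estimated correlation). There PPP1R15A, a phosphatase subunit that reverses eIF2-alpha phosphorylation, rose 2.70-fold, DDIT3 2.54-fold (log2 0.75 ± 0.19 after the correction, from 1.35) and ATF4 2.07-fold. In that list, with a median of 0.56, 13 rose and 2 fell after the correction (median 0.51) and 18 and 1 without NAT10 replicate 2. In the list of inflammatory cytokines and NF-kB targets 7 of 27 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.000131; adjusted p = 0.297 with an estimated correlation), with a median of 1.05, and with 10 and 2 after the correction (median 0.83) and 13 and 3 without NAT10 replicate 2. The NF-kB subunits RELB and NFKB2 rose 2.59-fold and 2.29-fold and the cytokine IL1B 2.17-fold, while TNFAIP2 fell 2.78-fold and CSF1 fell by 0.76 on the log2 scale.

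Interferon-stimulated genes split. Of 39 tested, 10 rose and none fell (12 and 2 adjusted over the list alone), and 29 did not pass. Beside OASL, the antiviral enzyme RSAD2 rose 9.49-fold, IFI6 7.94-fold and ISG15, a ubiquitin-like modifier, 6.61-fold. The list median was 0.36 (camera adjusted p = 0.00447; adjusted p = 0.313 with an estimated correlation). Without NAT10 replicate 1, 16 members rose, and without NAT10 replicate 2, 15 rose, 7 fell and the list no longer passed although its median was 0.56 (camera adjusted p = 0.0782). After the correction 15 rose and 3 fell (median 0.28), with IFI6 at a log2 fold change of 2.12 ± 0.29 (SE), from 2.99, and ISG15 at 1.99 ± 0.14, from 2.72.

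Epidermal genes moved in both directions. In the list of keratinocyte differentiation and the cornified envelope, 7 of 22 tested members rose and 6 fell (7 and 7 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.821; median -0.19, direction of the test upward). SPRR2A, a cornified envelope precursor, rose 17.6-fold from 0.376 ± 0.0884 to 6.73 ± 1.32 CPM, and KLF4, a transcription factor of barrier formation, rose 4.01-fold from 13.8 ± 1.76 to 55.2 ± 4.33 CPM. KRT4 fell 14.96-fold, from 28.2 ± 8.54 to 1.89 ± 0.523 CPM, and IVL, which encodes the envelope protein involucrin, fell 9.25-fold from 4.55 ± 1.52 to 0.508 ± 0.251 CPM. Of 16 tested genes of hyperproliferative and psoriasis-associated epidermis, 6 rose and none fell (6 and 0 adjusted over the list alone; median 0.86, camera adjusted p = 0.000517; adjusted p = 0.297 with an estimated correlation). PI3, the elastase inhibitor elafin, rose 19.5-fold from a low level of 0.249 ± 0.244 CPM to 5.06 ± 0.435 CPM. The wound keratins KRT17 and KRT6A rose 3.55-fold and 2.18-fold, and S100A2 rose 3.31-fold. After the GC and length correction 5 of these rose and the list no longer passed (median 0.58, camera adjusted p = 0.101). The correction lowered the log2 fold changes of PI3 from 4.29 to 3.34 ± 0.61 (SE), of S100A2 from 1.73 to 1.02 ± 0.14 and of SPRR2A from 4.14 to 3.29 ± 0.25. Of 18 basal keratinocyte genes, 1 rose and 1, KRT15, fell 8.58-fold, from 576 ± 103 to 67.1 ± 18.3 CPM, while 16 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.793). After the correction 7 basal genes rose and 2 fell, and without NAT10 replicate 2, 4 rose and 4 fell. For differentiation the correction gave 6 and 7.

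**Figure D3:**
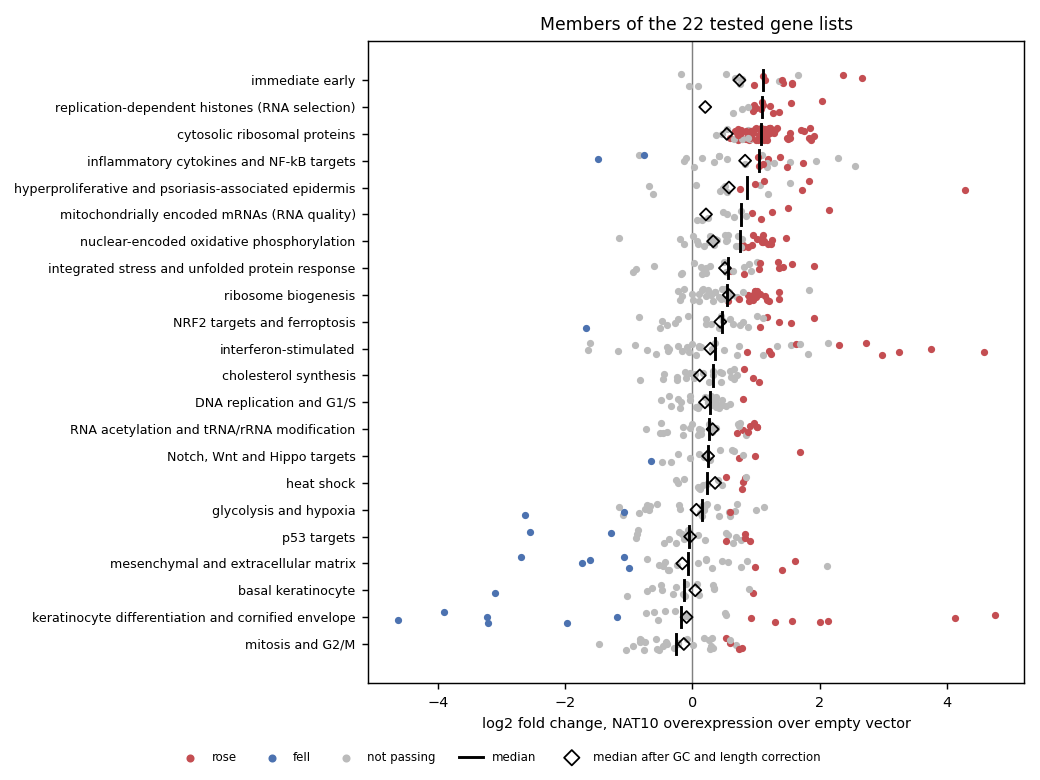
Log2 fold change, NAT10 over vector (horizontal axis), of each tested member of the 22 tested gene lists (rows); red points rose, blue points fell and grey points did not pass at an edgeR adjusted p under 0.05, with a black bar for the list median and an open diamond for the median after correction for GC content and length. The ribosomal protein median was 1.08 and became 0.54 after the correction, and differentiation genes lay on both sides of 0.

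Among the 12 largest rises by the rule set in advance were also KIFC1, CUTA, WDR38, INTS3 and SAA1. KIFC1, a mitotic kinesin (ENSG00000237649, chromosome 6, 33391536 to 33409924), was at 0.823, 0.665 and 0.696 CPM with vector and 0.969, 23.3 and 28.0 CPM with NAT10, a log2 fold change of 4.57 ± 1.09 (SE, edgeR adjusted p = 0.0366). CUTA (ENSG00000112514, chromosome 6, 33416442 to 33418317) was at 1.28 ± 0.386 and 14.8 ± 4.36 CPM. Both lie next to the histocompatibility region, where RPS18, another gene of that stretch, was counted at no more than 0.741% of the median of the other ribosomal protein genes in any library. SAA1, an acute-phase protein, rose 6.04-fold, INTS3 6.99-fold and WDR38 9.79-fold. Among the 12 largest falls were also OLFM4 and HPGD, an enzyme that inactivates prostaglandins, which fell 30.7-fold and 8.05-fold. OLFM4 went from 5.59 ± 3.38 to 0.164 ± 0.231 CPM, with 0 CPM in NAT10 replicate 1, so its fold is uncertain. CFI, a complement protease, fell 12.4-fold, SNCAIP 12.6-fold, METTL7A 9.41-fold, PADI3, a peptidylarginine deiminase, 8.34-fold, PLCE1 8.10-fold and SYTL2 7.74-fold. The log2 fold changes of CUTA, WDR38, SAA1 and PLCE1 went from 3.53, 3.29, 2.60 and -3.02 to 2.91, 2.68, 1.75 and -2.23 after the correction.

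Before the correction, mRNAs of nuclear oxidative phosphorylation genes and mitochondrially encoded mRNAs were also more abundant. The mitochondrially encoded list had been fixed in advance as a check of RNA quality. Of 37 nuclear genes of oxidative phosphorylation, 16 rose and none fell (24 and 0 adjusted over the list alone; median 0.75, camera adjusted p = 3.02e-08; adjusted p = 0.306 with an estimated correlation), and 15 rose and 2 fell after the correction, with a median of 0.33. Without NAT10 replicate 2, 30 of these nuclear genes rose and 1 fell, and 9 mitochondrially encoded mRNAs rose and none fell. NDUFB9 of complex I rose 2.77-fold, COX5A 2.14-fold, NDUFA4 2.02-fold and NDUFS3 1.94-fold. Of the 13 mitochondrially encoded mRNAs 5 rose and none fell (9 and 0 adjusted over the list alone; camera adjusted p = 1.20e-05; adjusted p = 0.306 with an estimated correlation), namely MT-ND1, MT-ND2, MT-ND3, MT-ND5 and MT-CO2, by 1.92-fold for MT-ND5 to 4.45-fold for MT-ND3. All mitochondrially encoded mRNAs together took 5.52%, 5.78% and 4.76% of the counts with vector and 8.46%, 6.27% and 7.85% with NAT10. Of 14 replication-dependent histone genes, whose mRNAs are typically but not always without a poly(A) tail, 11 rose and none fell (14 and 0 adjusted over the list alone). The median was 1.09 (camera adjusted p = 3.10e-08, adjusted p = 0.306 with an estimated correlation). HIST1H1E rose 4.09-fold, HIST1H1C 2.93-fold, HIST1H2BK 2.41-fold and HIST1H2AC 2.32-fold. After the correction neither of these lists passed (medians 0.21 and 0.20, camera adjusted p = 0.328 for the mitochondrially encoded and 0.0942 for the histone mRNAs): 4 mitochondrially encoded mRNAs rose and 2 fell, and 4 histone genes rose. MT-CO2 and HIST1H2BK no longer passed, at log2 fold changes of 0.56 ± 0.18 and 0.22 ± 0.09 (SE; edgeR adjusted p = 0.0530 and 0.0980). MT-ND3, MT-ND1, HIST1H1E and HIST1H1C were at 1.43, 0.48, 1.20 and 0.65 ± 0.10, from 2.15, 1.08, 2.03 and 1.55.

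Metabolic and chaperone lists shifted as well. Of 26 targets of the antioxidant factor NRF2 and ferroptosis genes, 5 rose (OSGIN1, FTL, NQO1, CHAC1 and FTH1) and 1, the aldo-keto reductase AKR1B10, fell 3.20-fold (8 and 1 adjusted over the list alone; camera adjusted p = 0.0154; adjusted p = 0.297 with an estimated correlation). NQO1 rose 2.10-fold, FTL, the ferritin light chain, 2.58-fold and OSGIN1 2.93-fold, and 11 rose and 1 fell after the correction (median 0.44, from 0.47), with FTL at a log2 fold change of 0.59 ± 0.11 (SE), from 1.37. Without NAT10 replicate 2, 14 NRF2 and ferroptosis genes rose and 4 fell. Of 15 heat shock genes, HSPA8, AHSA1, FKBP4 and HSP90AB1 rose, by 1.78-fold, 1.74-fold, 1.71-fold and 1.44-fold (4 and 0 adjusted over the list alone; camera adjusted p = 0.0291; adjusted p = 0.297 with an estimated correlation). Of 25 cholesterol synthesis genes, CYP51A1, EBP and NSDHL rose, by 2.06-fold, 1.95-fold and 1.76-fold (1 and 0 adjusted over the list alone; camera adjusted p = 0.0291; adjusted p = 0.508 with an estimated correlation). The desaturase SCD, among the 5 changed genes of highest level, fell 1.75-fold from 4821 ± 1199 to 2757 ± 67.8 CPM, and no longer passed after the correction (log2 -0.57 ± 0.20, edgeR adjusted p = 0.0646). The heat shock list, with a median of 0.22, no longer passed without NAT10 replicate 2 (median 0.40, camera adjusted p = 0.145) or after the correction (median 0.36, 0.101). The cholesterol list, with a median of 0.32, no longer passed without vector replicate 3 (median 0.22, camera adjusted p = 0.114), without NAT10 replicate 1 (median 0.25, 0.0678) or after the correction (median 0.12, 0.107). The cholesterol genes that rose numbered 1 without NAT10 replicate 1, 12 without NAT10 replicate 2 and 6 after the correction, the last 2 with 1 fall each, and 5 heat shock genes rose and 1 fell after the correction.

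Cell cycle genes showed few calls. Of 30 genes of DNA replication and G1/S only SLBP rose (1 and 0 adjusted over the list alone), although the list passed as a set (median 0.28, camera adjusted p = 0.0117; adjusted p = 0.306 with an estimated correlation; 0.0570 after the correction, where the median was 0.20 and 10 members rose and none fell). The helicase subunits MCM4 and MCM7 were at 458 ± 25.7 and 331 ± 40.2 CPM with vector and 603 ± 67.3 and 500 ± 99.1 CPM with NAT10. Neither passed, but both did after the correction (log2 0.46 and 0.45, edgeR adjusted p = 0.0179 and 0.00650). Of 32 mitotic genes UBE2C, CCNB1, PTTG1 and BIRC5 rose, by 1.66-fold, 1.45-fold, 1.51-fold and 1.72-fold (4 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.821; median -0.25, direction of the test upward). UBE2C and PTTG1 no longer passed after the correction, with log2 fold changes of 0.06 ± 0.08 and 0.02 ± 0.07 (SE), where 3 mitotic genes rose and 1 fell, and 1 mitotic gene rose without NAT10 replicate 1. Without NAT10 replicate 2, 15 replication genes rose and 1 fell, and 11 mitotic genes rose and 7 fell.

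The lists of p53 targets, of glycolysis and hypoxia, of mesenchymal and matrix genes and of Notch, Wnt and Hippo targets did not pass as sets (camera adjusted p = 0.619, 0.817, 0.935 and 0.0985). After the correction 6 rose and 5 fell, 4 and 6, 5 and 5, and 2 and 1 in these lists, in that order. Without NAT10 replicate 2 the numbers were 9 and 4, 8 and 5, 8 and 6, and 6 and 2. Without NAT10 replicate 1, 2 p53 targets rose and 2 fell, 1 glycolysis and hypoxia gene rose and 4 fell, and 4 mesenchymal genes rose and 3 fell. Of 24 p53 targets TRIAP1, AEN, PLK3 and TNFRSF10B rose and TP53INP1 and ZMAT3 fell, by 5.85-fold and 2.44-fold, with log2 fold changes of -1.94 ± 0.37 and -0.49 ± 0.13 (SE) after the correction (4 and 3 adjusted over the list alone; median -0.06, direction of the test upward). Of 30 glycolysis and hypoxia genes VEGFA rose 1.51-fold and CA9, a hypoxia-induced carbonic anhydrase, fell 6.18-fold, while PDK1 fell 2.11-fold but was at a log2 fold change of 0.040 ± 0.35 (SE) after the correction (1 and 2 adjusted over the list alone; mean -0.10, median 0.15). Of 24 mesenchymal genes PLAUR, MMP1 and CYR61 rose and LOX, MMP13, TNC, FN1 and ZEB2 fell (5 and 6 adjusted over the list alone), with the urokinase receptor PLAUR up 2.64-fold, the collagenases MMP1 up 3.08-fold and MMP13 down 6.48-fold, and LOX down 3.35-fold (log2 -1.15 ± 0.31 after the correction, from -1.74). Of 16 Notch, Wnt and Hippo targets ANKRD1, AMOTL2 and CYR61 rose, by 3.23-fold, 1.66-fold and 1.97-fold, and NOTCH1 fell 1.58-fold (3 and 1 adjusted over the list alone), and this list passed without vector replicate 3 (camera adjusted p = 0.0286). CYR61, FN1 and ZEB2 no longer passed after the correction, at log2 fold changes of 0.72 ± 0.25, -0.60 ± 0.24 and -0.80 ± 0.40 (edgeR adjusted p = 0.0616, 0.0935 and 0.158).

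Markers of other cell types were at low levels, and those that passed on all libraries without the correction fell. Of 4 tested fibroblast markers, COL3A1 and FBLN1 fell (1 and 2 adjusted over the list alone), FBLN1 2.26-fold from 20.1 ± 2.28 to 8.91 ± 2.20 CPM. MFAP5, another of them, was at 1.65 and 3.34 CPM on average with vector and NAT10 and rose after the correction (log2 1.33 ± 0.31, edgeR adjusted p = 0.0180) and without NAT10 replicate 1 (edgeR adjusted p = 0.0380). Of 3 melanocyte markers EDNRB fell (0 and 2 adjusted over the list alone). No melanocyte marker fell without NAT10 replicate 1 or after the correction and 2 did without NAT10 replicate 2, and MITF and PMEL averaged 4.25 and 1.02 CPM over the 6 libraries. Of 3 endothelial markers VWF and CDH5 fell (0 and 2 adjusted over the list alone), CDH5 2.47-fold. None of 4 leukocyte markers passed (0 adjusted over the list alone), with CORO1A at a mean of 3.44 CPM and LAPTM5 at 1.15 CPM. The leukocyte marker CSF1R rose without NAT10 replicate 2 (edgeR adjusted p = 0.0472). No nuclear noncoding RNA was tested, since the table used holds protein-coding genes. SLBP, CSF1, CHAC1, FTH1, PLK3, TNFRSF10B, TNC, FN1, ZEB2, EDNRB, MFAP5, CSF1R and the calls without vector replicate 3 lay outside the rule for named genes and were named after their values were seen.

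Genes with near-identical relatives or many processed copies, among them the ribosomal protein, histone and ferritin genes, SPRR2A, KRT6A, KRT17, SAA1, HSPA8 and the mitochondrial genes, are uncertain where the counting split or dropped shared reads. Genes that overlap another gene are uncertain as well, because the strand setting of the counting is not given in the sources used here.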

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

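The DESeq2 and correction fits with libraries left out, and the correction with the block, were chosen after the results were seen; the other alternatives were planned. DESeq2 called 2911 genes (1704 up, 1207 down), and the GC and length correction 3898 (2196 up, 1702 down), of which 1473 were also called without it in the same direction. An adjusted p under 0.01 left 30 genes and under 0.1 gave 3177. A fold of 1.5 gave 1746, and glmTreat against that fold 141. With 1 library left out, counts ran from 0 in edgeR to 6349 in DESeq2 (rises 0 to 3147, falls 0 to 3202, at least 2-fold 0 to 2941), and called lists from 9 to 16. No call changed sign in edgeR or DESeq2 with a library left out or under another scaling, while 37 did after the correction (14 to 57 with a library left out too). A gene whose groups do not overlap can hardly change sign when a library is left out, so the lack of sign changes there says little. NAT10 had log2 fold changes of 0.49 with DESeq2 and 0.41 after the correction, and 0.37 to 0.57 with a library left out. All 22 tested lists kept their call under DESeq2, both other scalings, both filters, limma-voom and the block. The estimated correlation left 0 lists, and the correction with the preset correlation left 9. With the correction and the estimated correlation together no list passed (lowest camera adjusted p = 0.556). Under the correction with the preset correlation 6 lists lost their call. Their medians were 0.58 (psoriasis), 0.20 (G1/S), 0.36 (heat shock, from 0.22), 0.12 (cholesterol), 0.21 (mitochondrially encoded) and 0.20 (histones). With a library left out these medians ranged from 0.36 to 1.05, 0.17 to 0.41, 0.17 to 0.41, 0.048 to 0.56, 0.10 to 0.99 and 0.13 to 1.36, those of interferon-stimulated genes from 0.27 to 0.56 and of Notch, Wnt and Hippo targets from 0.15 to 0.43. PDK1 alone among the named genes reversed, from -1.08 to 0.040 after the correction (-1.22 to 0.28 with a library left out). The correction used a PDK1 transcript of 14193 bases and 39.8% GC content, where the 10% longest transcripts had a median of 9671 bases. Whether that transcript is the one expressed was not tested, nor was another cause of the reversal. The labels do not say whether libraries with equal numbers were made together. Deviations of equal-numbered libraries correlated at 0.60, 0.11 and -0.01, and vector replicate 3 correlated best with NAT10 replicate 2 (0.50). These values cannot decide whether the libraries were paired. With the replicate block edgeR called 1931 genes, and with the correction too 3941 (2231 up, 1710 down), 9 lists and a NAT10 log2 fold change of 0.41, with the same 6 list medians at 0.63, 0.20, 0.35, 0.10, 0.20 and 0.19. The choice of pseudocount did not apply to counts, and a protein-coding subset was the whole table. NAT10 replicate 3, at 18143628 counts, limited the depth of its group.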

Other observations

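The tests of pathway and process terms and the RPS18 test were chosen after the results were seen; the splits, matched lists and left-out libraries were planned before them. Among 742 biological processes of the table's annotation, genes of mitochondrial translation rose most broadly of the terms named here: of 98 tested, 48 rose and none fell (camera adjusted p = 6.61e-15; adjusted p = 0.721 with an estimated correlation). MRPS18C of the mitochondrial ribosome rose from 33.3 ± 2.09 to 75.6 ± 4.996 CPM (SD, n = 3) and MRPL20 from 27.2 ± 1.58 to 73.3 ± 13.3 CPM. Of 123 spliceosome genes 34 rose and none fell (camera adjusted p = 4.85e-08; adjusted p = 0.709 with an estimated correlation), LSM6 from 14.0 ± 1.62 to 38.04 ± 3.28 CPM. Of 38 proteasome genes 12 rose and none fell (camera adjusted p = 3.90e-05; adjusted p = 0.709 with an estimated correlation), with PSMB7 up 2.37-fold and PSMC3 2.08-fold. After the GC and length correction 53, 65 and 16 genes of these terms rose and 0, 1 and 1 fell, and the median log2 fold changes went from 0.68, 0.41 and 0.54 to 0.38, 0.39 and 0.26. PSMB7, PSMC3 and MRPL20 were then at 0.60, 0.60 and 0.75, from 1.24, 1.05 and 1.43.

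Genes of homophilic cell adhesion moved the other way. Of 65 tested, 26 fell and 3 rose (camera adjusted p = 1.86e-08; adjusted p = 0.721 with an estimated correlation), and 31 fell and 5 rose after the correction, with the median going from -1.02 to -0.65. CELSR2 fell from 90.9 ± 13.5 to 37.1 ± 4.57 CPM, and its log2 fold change shrank from -1.29 to -0.81 ± 0.13 (SE) after the correction. FAT2, which fell from 1207 ± 106 to 561 ± 5.58 CPM, and PCDH7 did not pass after it, at -0.39 ± 0.17 and -0.40 ± 0.18, from -1.10 and -1.06 (edgeR adjusted p = 0.122 and 0.127). Of 46 ECM-receptor genes 13 fell and 1 rose (camera adjusted p = 0.00385; adjusted p = 0.709 with an estimated correlation), among them HSPG2, a basement membrane proteoglycan, from 101 ± 4.72 to 42.4 ± 5.03 CPM (log2 -1.25, and -0.73 after the correction). After the correction 15 of these fell and 7 rose, and the median went from -0.60 to -0.26. Negative chemotaxis, with 17 tested genes, had 5 falls and no rise (camera adjusted p = 0.00242; adjusted p = 0.721 with an estimated correlation), and 11 falls after the correction, with the median at -0.62 against -0.64. With an estimated correlation and no GC and length correction, camera called 0 of the 742 biological processes and 0 of the 218 pathway terms. The counts that follow used the preset correlation. Of the 25 biological processes called down by camera, 9 were still called down after the correction. Of the 72 called up, 59 were still called up. Among 218 pathway terms the balance differed: of 5 called down 4 were still called down, and of 12 called up 7 were still called up. After the correction 10 pathway terms in all were called down and 8 up.

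Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many changed genes (1794, highest of the others 0), as many changed by at least 2-fold (991, highest of the others 0) and as many called lists (15, highest of the others 13). In camera with the preset correlation, the splits that mix the groups called from 5 to 13 lists, with 0 genes called by edgeR. A list call with that correlation can therefore arise when the groups are mixed. With 10 splits no share under 0.05 can be reached.

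Cytosolic ribosomal protein mRNAs had a median log2 fold change of 1.08 (0.54 after the correction). In 10000 lists matched on transcript length, GC content and level the median was 0.75 and the upper bound of the central 95% was 0.888. These values argue for the traits as part of the rise. Length and GC content came from the longest protein-coding transcript, 7072 bases for RPL14, which need not be the one expressed. Members may thus have been matched to unlike genes, so the test cannot decide whether these traits are the whole of the rise. Leaving out 1 NAT10 library gave a median of at least 0.964, which argues against a single library. NAT10 overexpression and other differences between the groups of libraries stay open and untested, and may act together.

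Immediate early mRNAs had a median of 1.12 (0.74 after the correction), against a bound of 0.421 in matched lists, and of at least 1.01 with 1 NAT10 library left out. The value with 1 NAT10 library left out argues against a single library as the whole cause. The matched lists argue against level, and length and GC content of the longest protein-coding transcript, as the whole cause. Where another transcript is expressed, members may have been matched to unlike genes, as for the ribosomal proteins. The matched lists thus cannot decide about the traits of the transcripts expressed. An effect of NAT10, or of handling or transfection that differed between groups, could stand behind the pattern and was not tested.

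KIFC1 and CUTA, next to the chromosome 6 histocompatibility region, were among the largest rises. RPS18, a ribosomal protein gene there, reached at most 0.741% of the median of the other ribosomal protein genes, where that class is abundant. A candidate explanation is that reads shared with alternate copies of the region were dropped in counting, which could leave few, uneven counts for these genes. It does not by itself give a difference between groups, and a biological rise stays open and untested.

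NAT10 replicate 3 alone held 15.5 CPM of COL5A2, 6.14 CPM of VIM and 15.1 CPM of PEG10, and 25 counts of LYZ, against at most 0.560, 0.784 and 3.74 CPM and 2 counts in the others.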
